A study of Mus musculus with 6 samples.

How the data were processed

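Total RNA from 6 sorted bone marrow samples of female C57BL/6 mice aged 7 weeks was measured on single-colour Illumina BeadChip arrays, with a separate array for each sample. The labels place 3 arrays in the CCR9+ plasmacytoid dendritic cell (pDC) group and 3 in the group of pDC-like precursors without CCR9, and the series design describes independent isolations. Cells were obtained by FACS sorting, RNA was isolated with a mirVana kit and labelled with a TargetAmp-Nano kit, per the labels' protocols. The sorting gates beyond CCR9 are not given in the sources used here.

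The authors deposited a non-normalized table of linear intensity per probe, which averages the beads of a probe, together with a detection p-value per probe and array, per the file headers. The submitters' processing notes name BeadStudio and lumi, and their versions are not given in the sources used here. A detection p-value states how often negative control beads of the same array were as bright as the probe. The authors also deposited a processed value table of these 45281 probes. Its values are intensities on a linear scale, judged from their range and from a rank correlation of at least 0.9997 between each processed column and the non-normalized column of the same array. After centring each probe over the arrays, every processed column correlated better with its own array (r from 0.843 to 0.997) than with any other (highest r 0.703). The medians of the processed columns lay between 153.3 and 153.96. Its normalization method is not given in the sources used here, and whether a background correction was applied is not stated, so it served as an alternative only. The medians of its columns lay within the range of the non-normalized medians (135.9 to 163.6), so its values still carried a background level.

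Depth on an array is the signal over background. The median probe signal ranged from 135.9 to 163.6 between arrays, and 15254 to 16905 probes per array had a detection p-value below 0.05. The number of arrays, 3 per group, limits the precision of every value.

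Background was corrected from the detection p-values with the normexp model of limma's neqc procedure (offset 16), followed by quantile normalization and log2 transformation, in R 4.3.3 with limma 3.58.1 and the R package data.table (version 1.17.8). Probes with a detection p-value below 0.05 on at least 3 of the 6 arrays were kept, which left 16857 probes. Gene names came from the platform annotation supplied for the probes: 34885 probes had 1 gene symbol, 18 had several and were left unnamed, and 10378 had none there. Through their Entrez identifiers, 34807 probes were matched in the RefSeq gene table of assembly GRCm38.p6, which was used for names only; no coordinates are printed because no genome build is named for the array. Among the kept probes, 14282 had 1 symbol. Each gene was represented by its kept probe with the highest mean signal, which gave 9561 genes; 3337 genes had more than 1 kept probe, 12 of them had probes called in opposite directions, of which 1 is named here (H2bc21).

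Group differences were fitted for every gene with limma's lmFit and eBayes on the log2 values of all 6 arrays, with no replicate term, and p-values were adjusted with the Benjamini-Hochberg method over the 9561 genes. The fit had 4 residual degrees of freedom and 2.63 prior degrees of freedom. All log2 fold changes are the CCR9- pDC-like precursor mean minus the CCR9+ pDC mean, so negative values are higher in CCR9+ pDCs. An adjusted p below 0.05 is the threshold throughout. Every adjusted p-value of a gene is from this limma fit, or from limma under the alternative named beside it. Where none of a gene's probes was above background on any array of 1 group, its fold is given as a lower bound. Where some but not all arrays of a group were above background, the fitted fold is given with their number, and it rests partly on signals that were not above background. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of 2 values: the lowest normalized signal among detected probes and the probe's own signal.

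In all, 27 gene lists were fixed before the data were examined, covering dendritic cell genes, pathways and markers of other cell types that a bone marrow sort could hold. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists; camera with an estimated correlation and fry were alternatives. Members called are counted over all genes tested and, separately, adjusted over the list alone. The genes named in the text were fixed by rule beforehand: Ccr9; the 12 highest and 12 lowest log2 fold changes among called genes whose groups do not overlap; up to 4 called members of each list with the largest change; and 15 genes of dendritic cell biology or proliferation whatever their result. The rule gave 124 tested genes. Clone and model names were to be counted and not named: 77 were among the called genes and none ranked among the 12 highest or lowest. A further 56 genes were named after their values were seen: the members of any list with at most 5 called in a direction, the largest changes in lists added later and the most abundant markers of other cell types. Mki67 was not analysed here.

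The procedure was tested on simulated data. In 20 simulations of the 9561 genes with the measured means and spread, 200 genes were changed. Of genes changed 1.5-fold, 35.9% were called; the shares were 58.4% for 2-fold and 92.7% for 4-fold changes. Called changed genes had the right sign in 100% of cases, and on average 6.55 unchanged genes were called per simulation. With no gene changed, at most 1 gene was called in a simulation. The data gave 3420 called genes, and the adjusted threshold depends on the share of changed genes. The simulated shares therefore need not hold for the data. Noise was drawn independently for each gene, without correlation between genes.

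Alternatives comprised the replicate number as a block, leaving out each array, no background correction (signals at least 16), offset 50, cyclic loess, median scaling, the authors' processed values, no filter on dim probes, detection on all 6 arrays, a detection p-value below 0.01, the mean of a gene's probes, an intensity trend with a robust prior, and array weights. A BeadChip term could not be included because the tables used here do not place the arrays on chips. The fit without both arrays numbered 3 was chosen after seeing the data.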

Results

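Gene expression was profiled in 2 sorted populations of mouse bone marrow: CCR9+ plasmacytoid dendritic cells (pDCs), which specialise in type I interferon production, and pDC-like cells without CCR9, which the series describes as common dendritic cell precursors. CCR9 is a chemokine receptor. Each population was represented by 3 arrays from independent isolations. Between 15254 and 16905 of 45281 probes were above background on an array, and the fewest were on CCR9+ pDC replicate 3. That array also correlated least with its own group, at a mean r of 0.976 over genes against 0.983 and 0.986 for the other CCR9+ pDC arrays and 0.992 to 0.993 for the CCR9- arrays.

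The comparison asks which genes distinguish the CCR9- pDC-like precursors from the CCR9+ pDCs. Precursor arrays had higher signals of cell cycle genes and of Bcl2, which protects cells from apoptosis. They also had higher signals of Zbtb46, a transcription factor of the conventional dendritic cell lineage. Of 9 such factors tested, 2 rose and 4 fell. CCR9+ pDC arrays had higher signals of major histocompatibility complex (MHC) class II genes. Also higher there were many pDC surface and function genes, such as Klk1 and Lag3, and macrophage genes such as C1qb, Mrc1 and Vcam1. Signals of the pDC transcription factors Tcf4 and Irf8 did not differ detectably. Of 9561 genes tested, 3420 passed the threshold, 1737 higher and 1683 lower in precursors. Of these, 1221 differed at least 2-fold, 555 higher and 666 lower. The groups did not overlap for 4868 genes (50.9%), where chance gives 10%. Under median scaling the median of all genes moved from 0.02 to 0.19, and the calls split into 2124 higher and 986 lower (68.3% higher, against 50.8%). Fold sizes depend on the background: of 180 genes chosen to be named, 68 moved toward 0 by over 1.5 times without background correction and 67 with the authors' processed values, and all of these were still called.

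Upk1b, which encodes the tetraspanin uroplakin 1B, had the largest increase in precursors. Its signal was 10.18 ± 0.05 (log2, SD, n = 3) in precursors, while no CCR9+ pDC array had it above background, so it was at least 25.3-fold higher (limma adjusted p = 1.34e-06). Col23a1, a transmembrane collagen gene, rose by 3.70 on the log2 scale (adjusted p = 0.000519) and was above background on 2 of the 3 CCR9+ pDC arrays. With probe means the log2 fold changes were 2.32 for Col23a1 and 2.69 for Bcl2. Bcl2 rose 12.2-fold, from 7.08 ± 0.07 to 10.69 ± 0.03 (log2, SD, n = 3; limma adjusted p = 2.99e-06). Bex6, above background on 2 of the 3 CCR9+ pDC arrays, rose 10.7-fold and Pclaf, which encodes a factor bound to the replication clamp PCNA, 9.71-fold. Slc34a1, a sodium-phosphate cotransporter gene, was at least 7.02-fold higher and not above background on any CCR9+ pDC array. Ngfr, the p75 neurotrophin receptor gene, rose 8.46-fold and was above background on 1 CCR9+ pDC array. Stmn1, whose product destabilises microtubules, rose 8.31-fold and was above background on 2 CCR9+ pDC arrays. The histone genes H2ac12, H2ac11, H2ac15 and H2ac21 rose 8.28- to 8.84-fold, but these paralogs are nearly identical in sequence and their probes cannot be assumed to separate them. Without CCR9+ pDC replicate 3 their log2 fold changes were 2.41, 2.49, 2.43 and 2.46, and all 4 were still called.

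The lowest fold changes belonged to genes high in CCR9+ pDC arrays. C1qb, a complement C1q subunit gene, fell from 11.77 ± 0.47 to 5.62 ± 0.27 (log2, SD, n = 3), a 70.9-fold difference (limma adjusted p = 1.60e-05), and was above background on 2 of the 3 precursor arrays. Fcna, a ficolin gene, was 52.6-fold lower in precursors, the mannose receptor gene Mrc1 52.3-fold and the adhesion molecule gene Vcam1 47.4-fold. Spic, a transcription factor of iron-recycling macrophages, was 40.0-fold lower, C1qc 39.4-fold, the lipoprotein lipase gene Lpl 38.0-fold, the receptor tyrosine kinase gene Axl 35.1-fold and the transporter gene Slco2b1 30.2-fold. With the mean of a gene's probes the log2 fold changes of Axl, Spic and Vcam1 shrank from -5.13, -5.32 and -5.57 to -2.67, -3.67 and -3.65. Spic and C1qc were above background on 2 of the 3 precursor arrays. Pgam2, a phosphoglycerate mutase gene, was at least 23.5-fold lower and not above background in precursors. The kallikrein genes Klk1b5 and Klk1b26 were 36.4- and 33.6-fold lower, with the caution that the Klk1 family consists of close paralogs.

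**Figure D1:**
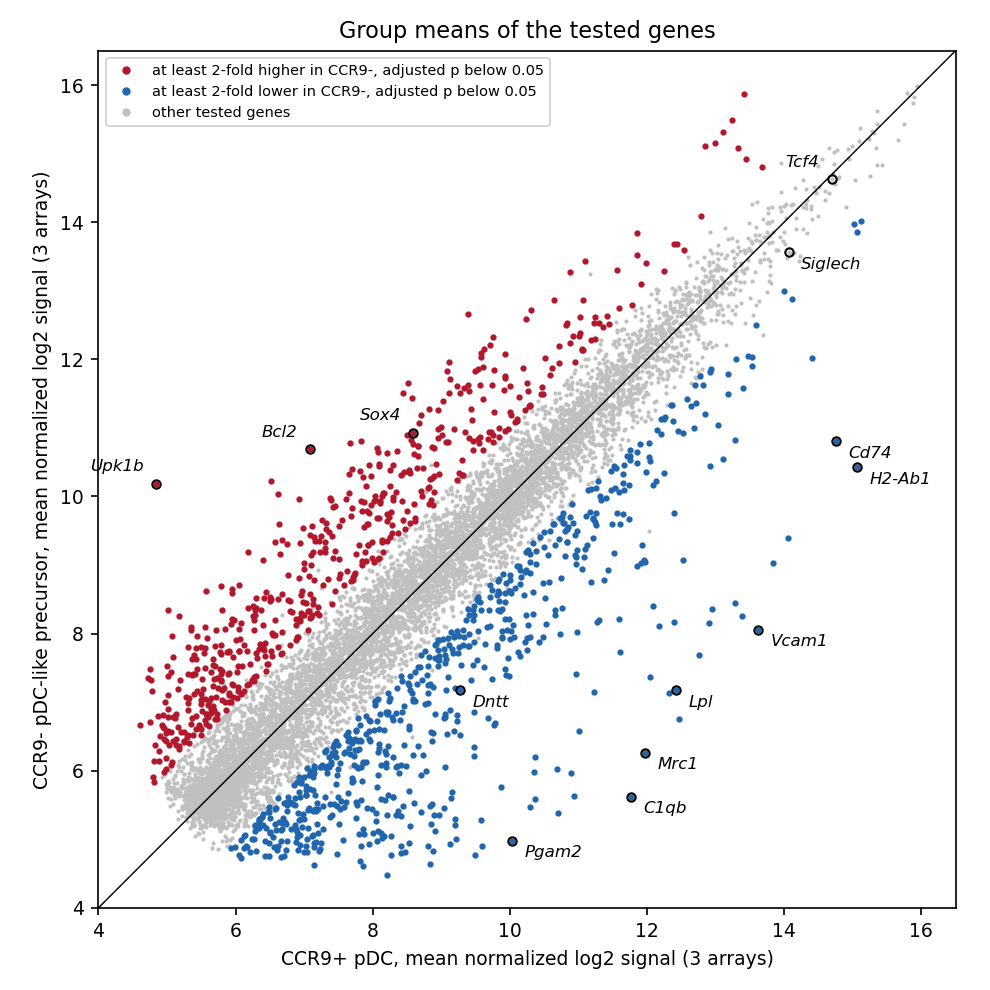
Mean normalized log2 signal of each tested gene in CCR9- pDC-like precursors (y axis) against CCR9+ pDCs (x axis), 3 arrays per group, with the line of equality. Red and blue points are the 555 genes at least 2-fold higher and the 666 at least 2-fold lower in precursors at an adjusted p below 0.05, and grey points are all other tested genes; Tcf4 lies near the line, Upk1b far above it and C1qb far below it.

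The sort was on CCR9, so its transcript would check the labels. The Ccr9 probe was not above background on any of the 6 arrays (lowest detection p-value 0.0919). No fold is given, the gene was not tested, and its signal checks nothing about the labels. Neither of the 2 probes of Flt3, the receptor for a dendritic cell growth factor, was above background (lowest detection p-value 0.0545).

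Transcription factors of the pDC lineage did not move one way. Of 10 tested, 2 rose (Cbfa2t3 2.50-fold and Myb 2.13-fold, the latter above background on 2 CCR9+ pDC arrays), 2 fell (Irf7 2.89-fold and Tsc22d1 2.06-fold) and 6 did not pass the test, with the same counts adjusted over the list alone. Their median log2 fold change was 0.02 and their mean 0.04, while camera's direction was down (adjusted p = 0.749), and the median turned negative under cyclic loess and with the authors' processed values. Tcf4, the E protein that pDCs depend on, had signals of 14.70 ± 0.26 in CCR9+ pDCs and 14.63 ± 0.10 in precursors (log2, SD, n = 3; limma adjusted p = 0.747); the log2 difference of -0.07 became 0.14 under median scaling. Irf8 differed by 0.10 (adjusted p = 0.610), and by -0.070 with the authors' processed values. Spib differed by -0.31 (adjusted p = 0.112). The Myb call was lost without any 1 of the precursor arrays (adjusted p = 0.0567, 0.0656 and 0.0574 without replicates 1, 2 and 3). That of Cbfa2t3 was lost without any 1 of the precursor arrays (0.131, 0.119 and 0.0833) and without CCR9+ pDC replicate 2 (0.0848), and also under cyclic loess (0.0522), with an intensity trend and robust prior (0.110), with probe means (0.0535) and with no filter on dim probes (0.0638).

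Surface and function genes of pDCs were mostly lower in precursors. Of 21 tested, 15 fell, 2 rose and 4 did not pass (16 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -1.08. Klk1, a tissue kallikrein gene, fell 24.1-fold, and Lag3, an inhibitory receptor gene, 6.00-fold. Grm8 and Cd4 were at least 5.54- and 2.97-fold lower and not above background in precursors, and with probe means Grm8 differed by -2.35 on the log2 scale. Siglech, which encodes a pDC lectin, fell 1.42-fold, from 14.07 ± 0.21 to 13.56 ± 0.02 (log2, SD, n = 3; limma adjusted p = 0.0207). This call was lost without any 1 of the precursor arrays (adjusted p = 0.0639, 0.0721 and 0.0618) and without CCR9+ pDC replicate 1 (0.0562) or 2 (0.0692), and under median scaling (0.174). In a fit of every kept probe with a gene symbol, 2 Siglech probes were called, at log2 fold changes of -0.50 and -0.88. Bst2, a pDC surface antigen gene induced by interferon, differed by -0.64 and did not pass (adjusted p = 0.0673). The risers were Ly6d (1.34-fold) and the interleukin 3 receptor gene Il3ra (1.77-fold). The Ly6d call was lost without precursor replicate 2 (adjusted p = 0.0596) or CCR9+ pDC replicate 2 (0.0513) and with the authors' processed values (0.0721), and the Il3ra call without any 1 of the precursor arrays (0.0673, 0.0974 and 0.0594). As a list these genes were lower (camera adjusted p = 3.97e-07; adjusted p = 0.0559 with an estimated correlation). Monocyte and macrophage markers were lower in the same arrays (median -3.03), as were basophil (-1.70) and granulocyte markers (-1.10).

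Genes of conventional dendritic cells moved both ways. Zbtb46 was not above background on any CCR9+ pDC array and was at least 3.88-fold higher in precursors (7.48 ± 0.10, log2, SD, n = 3, limma adjusted p = 1.48e-05). Only 1 of the 3 Zbtb46 probes was above background on any array. Itgax, the CD11c gene, rose 2.41-fold (adjusted p = 0.000662) and was above background on 2 of the 3 CCR9+ pDC arrays. Spi1, which encodes PU.1, rose 1.66-fold (adjusted p = 0.0293). Relb, an NF-kappaB subunit gene, fell 3.66-fold, and Batf3, a factor of cross-presenting dendritic cells, fell 2.28-fold and was above background on 1 precursor array; its call was lost without both arrays numbered 3, a fit chosen after seeing the data (adjusted p = 0.0630). Id2, an inhibitor of E proteins, fell 2.44-fold (adjusted p = 0.0443), and Bcl6 fell 1.54-fold (its call was lost under median scaling, adjusted p = 0.244). The Id2 call was lost without any 1 of the precursor arrays (adjusted p = 0.0806, 0.127 and 0.117) and without CCR9+ pDC replicate 1 (0.117) or 2 (0.119), under median scaling (0.0980), with an intensity trend and robust prior (0.0503) and with no filter (0.0619). The Spi1 call was lost without precursor replicate 1 (0.0902) or 2 (0.0697) and without CCR9+ pDC replicate 2 (0.0875) or 3 (0.0594), or both arrays numbered 3 (0.0695). In total 2 of the 9 conventional dendritic cell transcription factors tested rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.559, direction down, while fry's direction was up). Of the 12 surface and function genes tested, Itgax rose, while Cadm1, Cd209a, Sirpa, Ppt1 and Cd1d1 fell (2 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.138), and under median scaling Ppt1 and Cd1d1 no longer passed (adjusted p = 0.0770 and 0.188).

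**Figure D2:**
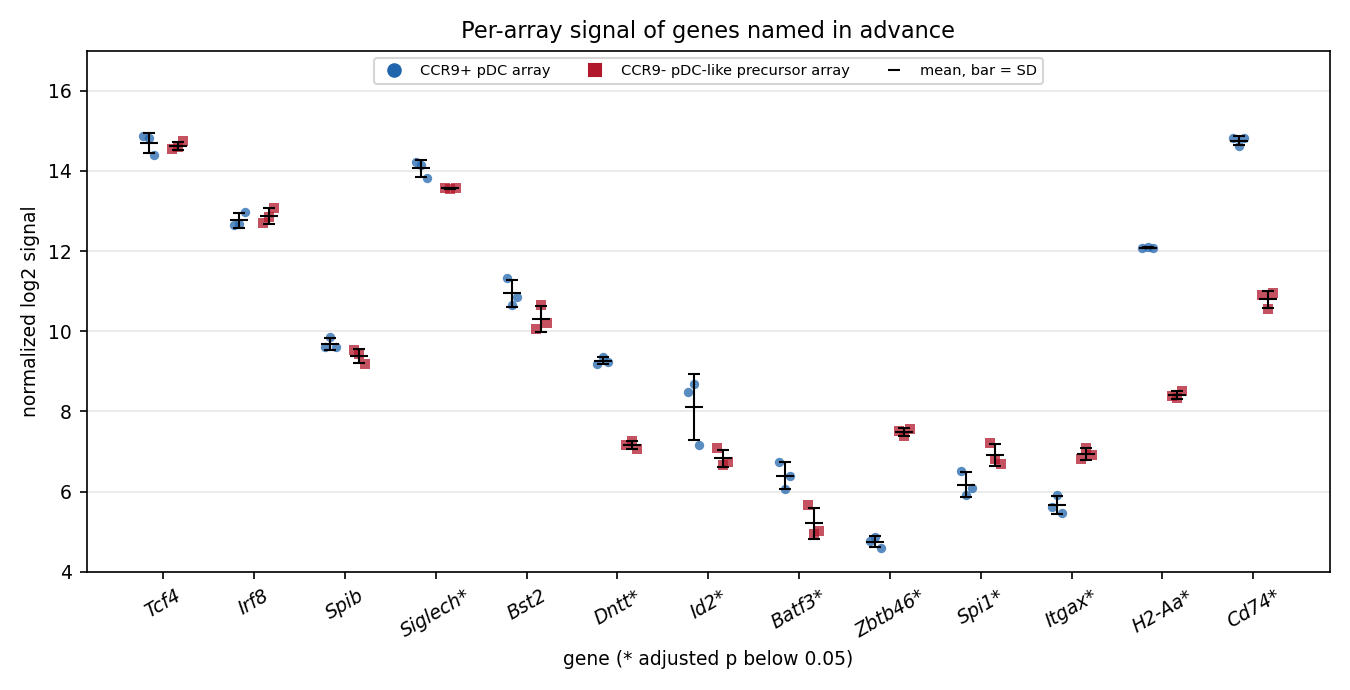
Normalized log2 signal (y axis) of 13 genes named in advance (x axis) on each array, CCR9+ pDC as circles and CCR9- pDC-like precursor as squares; horizontal marks are group means and bars are SD (n = 3). Tcf4 and Irf8 overlap between groups, Zbtb46 and Itgax are higher in precursors, and H2-Aa, Cd74 and Dntt are lower.

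Every tested cell cycle gene was higher in precursors. All 37 passed the test, over all genes and adjusted over the list alone, with a median log2 fold change of 2.26, a 4.80-fold difference. The mitotic kinesin genes Kif11 and Kif22 rose 6.37- and 5.93-fold, and Cdc6, which loads the replicative helicase, rose 5.92-fold. The list's mean signal was 10.62 ± 0.07 in precursors and 8.48 ± 0.08 in CCR9+ pDCs (log2, SD, n = 3), and 33 of the 37 genes were above background on every CCR9+ pDC array. Camera gave an adjusted p of 3.91e-25, and an adjusted p = 0.0707 with an estimated correlation.

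Progenitor genes were split. Among 19 tested haematopoietic and dendritic cell progenitor genes, 5 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.0613, and the list passed under 5 of 19 alternatives). Sox4 rose 5.05-fold and Cd93, a surface marker of early progenitors, 3.39-fold; the stem cell factor receptor gene Kit rose 1.87-fold. Myb, described above, and Meis1 (1.28-fold) were the other risers, and the Meis1 call was lost without precursor replicate 2 (adjusted p = 0.139) or 3 (0.121) and without any 1 of the CCR9+ pDC arrays (0.105, 0.0714 and 0.0593), under cyclic loess (0.0552), with probe means (0.133) and with no filter (0.0714). The Myb call was lost without any 1 of the precursor arrays (0.0567, 0.0656 and 0.0574). Gata2 fell 5.67-fold and Cebpe, a granulocyte factor gene, 2.62-fold. In the lymphoid and B-lineage list 9 of 15 genes fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.230 with an estimated correlation). Dntt, the terminal transferase gene, fell 4.27-fold (9.27 ± 0.08 to 7.17 ± 0.10, log2, SD, n = 3; limma adjusted p = 2.12e-05), Pou2af1 3.03-fold and Fcrla 2.82-fold. Blk and Cd22 rose 2.54- and 1.99-fold. Lower in the same precursor arrays were monocyte and macrophage (median -3.03), basophil (-1.70) and granulocyte markers (-1.10).

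Of 33 oxidative phosphorylation genes tested, 14 rose, by small amounts, and none fell (15 and none adjusted over the list alone), with a median log2 fold change of 0.33, led by Atp5o (1.58-fold), Ndufb7 (1.54-fold) and Cox5a (1.45-fold). The Ndufb7 call was lost without precursor replicate 1 (limma adjusted p = 0.0813) or 2 (0.0706) and without CCR9+ pDC replicate 1 (0.0653) or 2 (0.0710). Camera gave an adjusted p of 0.000111, and adjusted p = 0.111 with an estimated correlation. Ribosome biogenesis genes had a median of 0.27, and 6 of 19 rose, also adjusted over the list alone, with Gar1 at 1.75-fold and Nop56 at a log2 fold change of 0.59 (camera adjusted p = 0.0157; adjusted p = 0.203 with an estimated correlation). Of 20 cytosolic ribosomal protein genes, 2 passed over all genes, Rpl4 and Rplp0, and none adjusted over the list alone (camera adjusted p = 0.159); their median of 0.10 turned negative under cyclic loess and with the authors' processed values. Leaving out precursor replicate 1 ended both calls (adjusted p = 0.0710 for Rpl4 and 0.0564 for Rplp0), as did leaving out precursor replicate 3 (0.0640 and 0.0706) or CCR9+ pDC replicate 1 (0.0570 and 0.0570). Rpl4 was also lost without precursor replicate 2 (0.0681) and with probe means (0.106), and Rplp0 without CCR9+ pDC replicate 2 (0.0655). In glycolysis 3 of 15 genes rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.767), with Pfkp, Gapdh and Pgam1 higher (1.76-, 1.57- and 1.34-fold) and Aldoa, Slc2a3 and Pfkl lower (1.94-, 1.33- and 1.32-fold). The Pgam1 call was lost without any 1 array except precursor replicate 3 (adjusted p = 0.143 and 0.148 without precursor replicates 1 and 2, and 0.117, 0.0636 and 0.0676 without CCR9+ pDC replicates 1, 2 and 3). It was also lost under cyclic loess (0.0565), with the authors' processed values (0.0600), with an intensity trend and robust prior (0.0519) and with no filter (0.0750). The Slc2a3 call was lost without precursor replicate 1 (0.0829) or 2 (0.0736) or CCR9+ pDC replicate 2 (0.0722), and under median scaling Slc2a3 and Pfkl no longer passed (0.353 and 0.539).

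Most genes of the MHC class II list were lower in precursors. All 13 genes tested in this list passed, 11 lower and 2 higher, also adjusted over the list alone. The class II chain genes H2-Eb1, H2-Ab1 and H2-Aa fell 27.9-, 25.0- and 12.8-fold, and Cd74, the invariant chain gene, fell 15.5-fold, from 14.76 ± 0.12 to 10.80 ± 0.21 (log2, SD, n = 3; limma adjusted p = 1.15e-05). H2-DMa and Ifi30 rose 1.40- and 1.55-fold; the H2-DMa call was lost without precursor replicate 1 (adjusted p = 0.0501). The list's median was -0.81 (camera adjusted p = 6.96e-06; adjusted p = 0.182 with an estimated correlation). Costimulation and activation genes were also lower, 7 of 11, with 1 higher, also adjusted over the list alone (median -1.53; camera adjusted p = 0.000348; adjusted p = 0.0707 with an estimated correlation). The median was -0.87 without background correction, -0.89 with the authors' processed values and -0.53 with no filter on dim probes. Cd83, above background on 1 precursor array, fell 7.77-fold, Cd274 5.22-fold and Cd40 4.89-fold, Cd86 fell by 2.32 on the log2 scale, and Tnfsf9 was at least 1.53-fold higher in precursors. Markers of monocytes and macrophages were lower in the same arrays (median -3.03).

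Receptor and effector genes of innate immunity were mostly lower in precursors. In the list of C-type lectins and Fc receptors, 16 of 22 genes fell and 1 rose (17 and 1 adjusted over the list alone). Clec4a3, Clec4a1 and Fcgr4 fell 21.5-, 20.7- and 18.7-fold, and Klrk1, an activating receptor gene, rose 2.71-fold. The list's median was -1.49, or -1.24 with undetected genes at their bounds (camera adjusted p = 5.12e-09; adjusted p = 0.0780 with an estimated correlation), and became -0.89 without background correction and -0.88 with no filter. Of 20 cytokine and chemokine genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone). Cxcl9, Cxcl16 and Cxcl10 were at least 13.2-, 5.07- and 3.17-fold lower and not above background in precursors. Il12a, the interleukin 12 p35 gene, rose 4.38-fold (camera adjusted p = 3.27e-06; adjusted p = 0.0559 with an estimated correlation). Of 23 Toll-like receptor and nucleic acid sensing genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 3.97e-07; adjusted p = 0.0695 with an estimated correlation). Tlr13 fell 6.11-fold and Tlr4, above background on 2 precursor arrays, 5.50-fold, Tlr8 was at least 3.40-fold lower, and Sting1 rose 1.71-fold. Monocyte and macrophage markers moved with these lists (median -3.03), and some genes, among them Mrc1, Clec4a3 and Cd14, are members of both.

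In the type I interferon response list, 15 of 25 genes fell and none rose (16 and none adjusted over the list alone). Ifit3 fell by 4.09 on the log2 scale, Oasl2 5.10-fold and Oas2 4.71-fold (median -0.68; camera adjusted p = 3.97e-07; adjusted p = 0.111 with an estimated correlation). Lysosomal genes fell in 13 of 21 cases and rose in none, also adjusted over the list alone, led by Ctsa (14.7-fold, but a log2 fold change of -0.86 with probe means), Ctsl (7.22-fold, above background on 1 precursor array) and Cd63 (3.74-fold; camera adjusted p = 3.28e-06; adjusted p = 0.0559 with an estimated correlation). Monocyte and macrophage markers moved the same way as both lists (median -3.03, with 17 of 21 lower). Among 22 chemokine receptor and integrin genes, 8 fell and 4 rose (9 and 4 adjusted over the list alone; camera adjusted p = 0.132). Cxcr3 fell 5.74-fold, Ccr3 was at least 3.18-fold lower, and Itgax, Cxcr4, Selplg and Itgb7 rose. Endoplasmic reticulum secretory genes fell in 5 of 20 cases (4 adjusted over the list alone; camera adjusted p = 0.175). Their median of -0.15 became 0.0031 under median scaling. Xbp1, a secretory transcription factor gene, fell 1.70-fold, and Dnajb9, Dnajc3, Sec61a1 and Creld2 also fell. The Dnajb9 call was lost without precursor replicate 1 (adjusted p = 0.0502) or 2 (0.0512), and that of Dnajc3 without precursor replicate 1 (0.0996) or 3 (0.0920) or CCR9+ pDC replicate 2 (0.0908) or 3 (0.0574). The Sec61a1 call was lost without precursor replicate 1 (0.0565) or 3 (0.0633) or CCR9+ pDC replicate 1 (0.0531) or 2 (0.0649), and with probe means (0.0729). That of Creld2 was lost without precursor replicate 2 (0.119) or 3 (0.118) or any 1 of the CCR9+ pDC arrays (0.0797, 0.0611 and 0.0742), and with no filter (0.0627). Under median scaling Dnajc3 and Sec61a1 no longer passed (0.339 and 0.535), nor did Creld2. Immediate early and stress genes passed in 3 of 19 cases (1 adjusted over the list alone, camera adjusted p = 0.0703). The list passed under 6 of 19 alternatives, with the lowest camera adjusted p for the replicate number as a block (0.000109). Median scaling (0.00512) and no filter (0.0158) were among the others. The 3 genes were Ier3 (2.75-fold lower), Jund, above background on 2 precursor arrays, and Gadd45b. The Jund call was lost without precursor replicate 1 (adjusted p = 0.114) or 2 (0.104) or CCR9+ pDC replicate 2 (0.123) or 3 (0.105), and with no filter (0.0710). The Gadd45b call was lost without precursor replicate 1 (0.0573) or 2 (0.0736) or CCR9+ pDC replicate 1 (0.0599), and under median scaling (0.0672).

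Markers of other bone marrow cell types were present in both groups and were mostly lower in precursor arrays. Of 21 monocyte and macrophage markers, 17 fell and none rose (18 and none adjusted over the list alone), with a median of -3.03, or -2.65 with undetected genes at their bounds (camera adjusted p = 3.69e-11; adjusted p = 0.0781 with an estimated correlation). That median was -1.78 without background correction and with the authors' processed values, -2.45 with offset 50 and -1.70 with detection on all 6 arrays. All 19 neutrophil and granulocyte precursor markers fell, also adjusted over the list alone, over a narrow range from -1.61 to -0.57 (median -1.10; camera adjusted p = 4.17e-09; adjusted p = 0.207 with an estimated correlation). Their signals were high in both groups: Ltf, the lactoferrin gene, stood at 15.12 ± 0.22 in CCR9+ pDCs and 14.02 ± 0.11 in precursors, and S100a8 at 14.90 ± 0.06 and 14.22 ± 0.15 (log2, SD, n = 3). Lcn2 fell 2.69-fold and Chil3 2.85-fold. Erythroid markers fell in 6 of 9 cases, also adjusted over the list alone (median -0.80; camera adjusted p = 0.00779; adjusted p = 0.272 with an estimated correlation), and Hba-a1 stood at 15.36 ± 0.47 and 14.84 ± 0.29 (limma adjusted p = 0.174). Basophil, mast cell and eosinophil markers fell in 9 of 10 cases, also adjusted over the list alone, with a median of -1.70, or -1.56 at the bounds (camera adjusted p = 1.50e-05; adjusted p = 0.0617 with an estimated correlation); Prss34 fell 5.22-fold and Fcer1a, above background on 2 precursor arrays, 4.92-fold. The basophil list's median was -0.98 without background correction, -1.01 with the authors' processed values and -0.85 with no filter.

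Among 13 T and NK cell markers, 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0631, and the list passed under 7 of 19 alternatives). Ccl5 fell 2.68-fold, Nkg7 2.16-fold and Lat at least 2.24-fold. Cd28 and Cd3e also fell, and Cd7 rose. The Cd28 call was lost without precursor replicate 2 (adjusted p = 0.0590) or CCR9+ pDC replicate 1 (0.0955) or 2 (0.105), under median scaling (0.0723) and with no filter (0.0533). That of Cd3e was lost without precursor replicate 2 (0.0779) or 3 (0.0621) and with probe means (0.159), and that of Cd7 without precursor replicate 1 (0.0658) or 3 (0.0505) or CCR9+ pDC replicate 2 (0.0581). Of 8 plasma cell markers, 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.123): Mzb1, which pDCs also express, fell 7.59-fold, Slamf7 2.26-fold and Xbp1 1.70-fold, and Sdc1 was higher (limma adjusted p = 0.00246). No fold is given for Sdc1, because its fitted probe was not above background on any CCR9+ pDC array, while another of its probes was on 1.

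**Figure D3:**
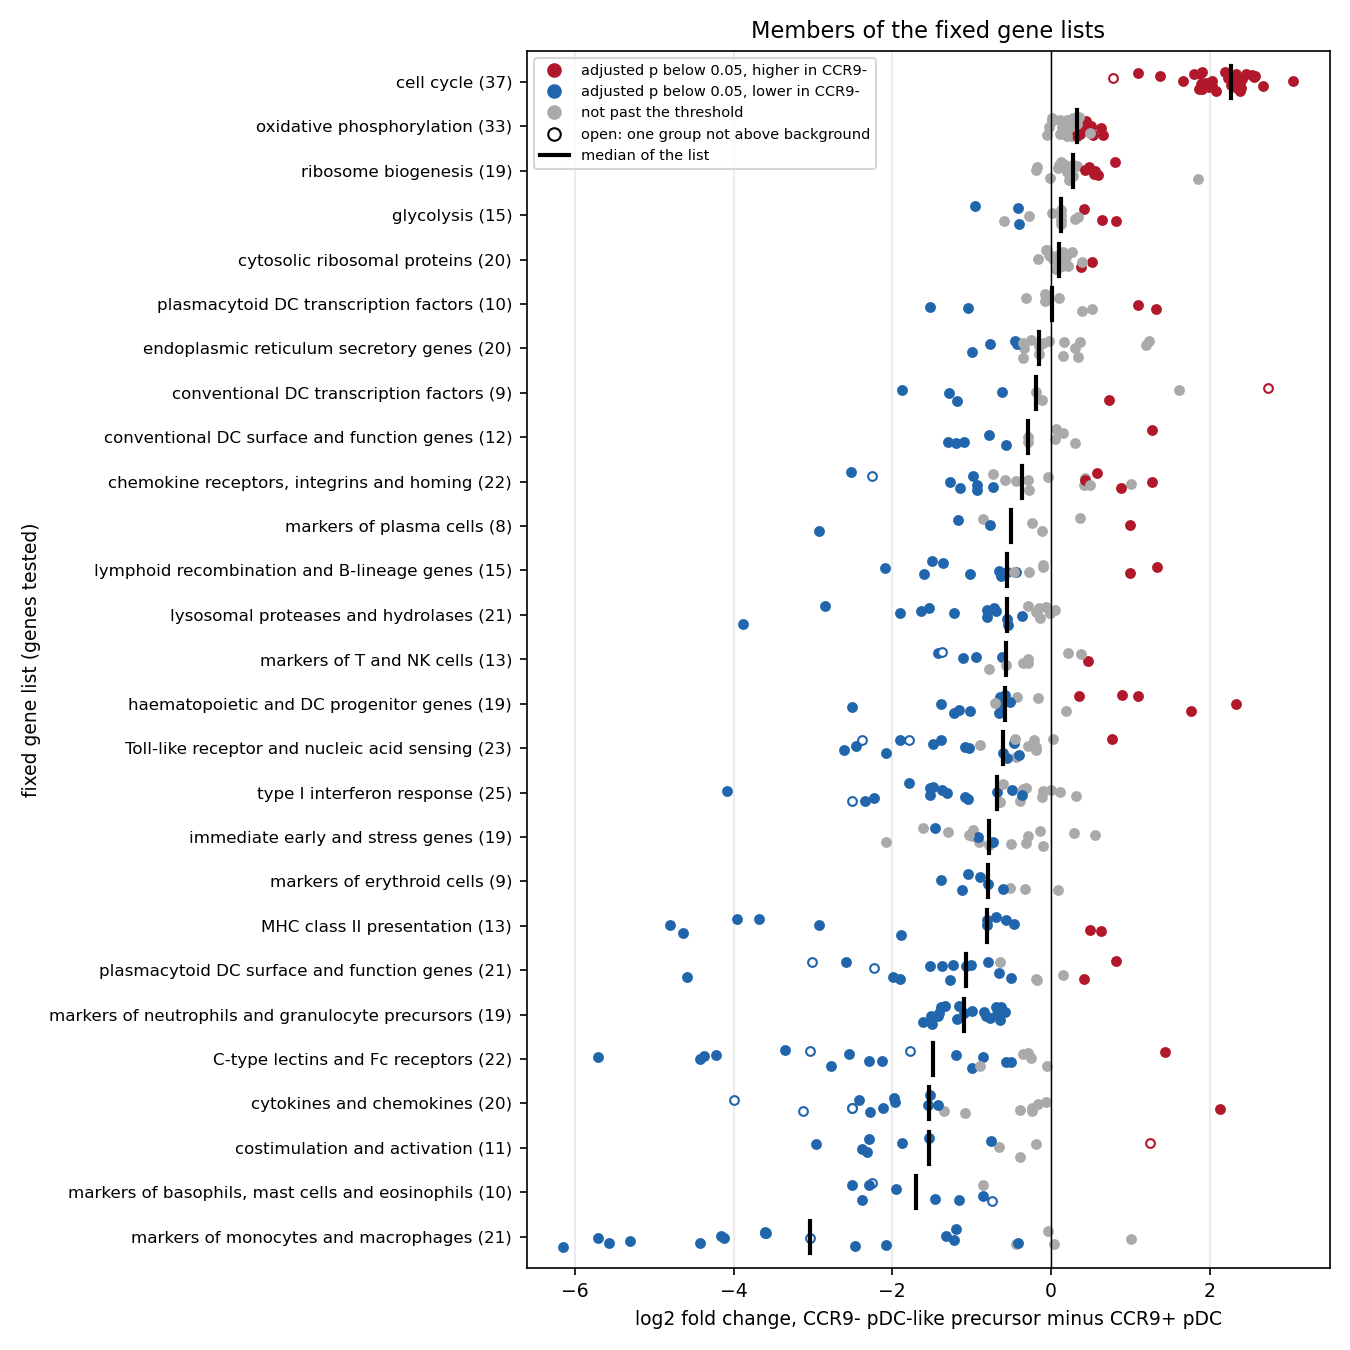
Log2 fold change (x axis, CCR9- pDC-like precursor minus CCR9+ pDC, 3 arrays each) of the tested members of the 27 fixed gene lists (y axis, ordered by median, with the number tested). Points are genes, coloured by direction where the adjusted p is below 0.05, open where 1 group was not above background, and black bars are list medians, from -3.03 for monocyte and macrophage markers to 2.26 for the cell cycle.

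With the preset correlation, 16 of the 27 lists passed, 3 higher and 13 lower in precursors; with an estimated correlation 0 passed, and 11 had an unadjusted p below 0.05. The loss of calls did not always come from a larger correlation. The estimate was -0.017 for pDC surface and function genes and -0.029 for cytokines and chemokines, both below the preset 0.01. Both lists still had a camera adjusted p of 0.0559 with it. Fry called 23 lists by its directional and 26 by its mixed test. Under median scaling 21 passed, gaining immediate early and stress genes (camera adjusted p = 0.00512), T and NK cell markers (0.0121), progenitor genes (0.0249), chemokine receptors and integrins (0.0249) and plasma cell markers (0.0420), each with a median below 0.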

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

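The test of these probes was chosen after seeing the data. Probes outside the comparison carried signal: 2575 probes above background on at least 3 arrays have no single gene symbol in the annotation used here. Tested as a set of their own with limma, 519 passed the threshold, 271 higher and 248 lower in precursors, and 238 of them differed at least 2-fold. Which transcripts they measure was not analysed here.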

How the results depend on the processing

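The fit without both arrays numbered 3 was chosen after seeing the data; it gave 3028 genes, 1231 of them at least 2-fold, and 19 lists, and of the genes named in the text it ended the calls of Abcg1 (0.0633), Batf3 (0.0630), Cd3e (0.0688), Cd7 (0.0687), Creld2 (0.158), Dnajc3 (0.131), H2bc21 (0.0650), Jund (0.0558), Meis1 (0.133), Mr1 (0.0978), Rpl4 (0.0802) and Spi1 (0.0695; limma adjusted p); it also lowered the log2 fold changes of Bex6 to 2.83 and H2ac12 to 2.55. The count of called genes stayed within 1.5 times the value of 3420 under the alternatives run, from 2442 (without precursor replicate 2) to 4256 (array weights). Leaving out 1 array gave 2442 to 3551 genes, 1183 to 1264 genes at least 2-fold and 16 to 19 lists. The 2-fold count fell from 1221 to 651 with no background correction and to 655 with the authors' processed values. Without background correction the background left in the signal compresses folds. The processed values also still carried a background level, but whether it lowered their count was not tested. Median scaling changed the split of calls to 2124 higher and 986 lower (68.3% higher against 50.8%) and the median of all genes from 0.02 to 0.19. Against that shift the oxidative phosphorylation median was 0.34, ribosome biogenesis 0.29 and MHC class II -0.75. The 16 lists called became 0 with an estimated correlation (11 at an unadjusted p below 0.05), 23 with fry's directional test and 26 with its mixed test, which ask other questions. It was 21 under median scaling and 20 with no filter; lists not called otherwise gained a call under 7 of the 19 alternatives (T and NK markers), 6 (immediate early and stress genes), 5 (progenitor genes), 3 (plasma cell markers) and 2 each (chemokine receptors, conventional dendritic cell surface genes).

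With the replicate number as a block, 3361 genes passed, 1241 of them at least 2-fold, and 18 lists, with immediate early and stress genes (camera adjusted p = 0.000109) and T and NK markers (0.0263) gained; Pgam1 (0.0594), Creld2 (0.0640) and Ndufb7 (0.0505) did not pass. Same-numbered arrays deviated together with correlations of 0.350, 0.044 and 0.242 over genes, and the arrays numbered 2 did not correlate best with each other, so the numbers were not taken to pair the samples.

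Over 180 genes chosen to be named and 19 alternatives, 3204 of 3374 values kept direction and side of the threshold, 155 lost the call, 11 gained it and 4 changed sign. The sign changes were Irf8 with the authors' processed values (-0.070), Tcf4 without CCR9+ pDC replicate 1 (0.018, range over arrays left out -0.22 to 0.018) and under median scaling (0.14), and H2bc21, the only called gene among them, with probe means (0.80), because its 2 detected probes moved apart. Of the called genes among the 180, 30 lost the call without at least 1 array and 145 kept it. Among the 27 fixed lists, medians changed sign only in lists that were not called: pDC transcription factors (-0.051 without precursor replicate 3, range over arrays left out -0.051 to 0.085, -0.024 with cyclic loess, -0.071 with the authors' processed values, -0.069 with detection on all 6 arrays, -0.013 with probe means), conventional dendritic cell transcription factors (0.090 without CCR9+ pDC replicate 3, range over arrays left out -0.39 to 0.090, 0.00028 with array weights, 0.0022 without both arrays numbered 3), endoplasmic reticulum genes (0.0031 under median scaling) and cytosolic ribosomal proteins (-0.0046 with cyclic loess, -0.12 with the authors' processed values). Of the 6 lists made after seeing the data, the medians of lipid handling, a called list (-0.20, and 0.0077 under median scaling), and of the BCL2 and caspase list (-0.24 to 0.44) also changed sign. For these medians the cause was not tested. Ccr9 had no value to vary, because its probe was not above background on any array. The BeadChip block was not run, since no chip is given. Signal over background limits dim genes: 128 called genes were not above background on any precursor array and 101 on any CCR9+ pDC array.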

Other observations

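Of the tests in this part, the comparison of macrophage with other markers, both dilution tests, the erythroid and granulocyte test and the test of pDC genes outside macrophages were chosen after the result was seen, as were 6 further gene lists. Permutation p-values in this part shuffle genes between lists and take genes as independent, so they measure no spread between arrays. Camera's estimated correlation between genes was 0.265 for the cell cycle list and 0.54 for granulocyte markers, so these p-values may be too small. Iron and haem genes were lower in precursors in 12 of 18 cases, with 1 higher, the transferrin receptor gene Tfrc (camera adjusted p = 4.46e-06; adjusted p = 0.0926 with an estimated correlation). The iron exporter gene Slc40a1 fell 25.5-fold, and the haem oxygenase gene Hmox1 was at least 8.36-fold lower. In lipid handling, Apoe fell 28.2-fold and Pparg 19.8-fold, each above background on 1 precursor array, and the sterol receptor gene Nr1h3 was at least 12.6-fold lower. Lpl and Abcg1 also fell, but 6 of 11 genes did not pass and the median was -0.20 (camera adjusted p = 0.00131; adjusted p = 0.0926 with an estimated correlation). The lipid median was 0.0077 under median scaling. Monocyte and macrophage markers moved with these genes (median -3.03), Cd163 and Trf belong to both the iron list and a core macrophage list described below, and Hmox1 is among the macrophage markers. Slc40a1, Hmox1, Spic, Lpl, Apoe, Pparg and Nr1h3 had been seen among the strongest changes before these lists were made.

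DNA repair genes of homologous recombination and the Fanconi pathway were higher in precursors in 20 of 22 cases and lower in none (median 1.44, or 1.35 at the bounds and 0.82 with the authors' processed values; camera adjusted p = 1.40e-10; adjusted p = 0.0882 with an estimated correlation). Rad54b, Rad51ap1 and Rad54l, already seen, rose 6.73-, 6.72- and 6.25-fold, and Brip1 5.27-fold; no Rad51ap1 probe was above background on more than 2 CCR9+ pDC arrays. Histone genes rose in 44 of 54 cases and fell in 3 (median 1.60, or 1.53 at the bounds and 0.90 with the authors' processed values; camera adjusted p = 6.52e-12; adjusted p = 0.0926 with an estimated correlation), with paralogs that probes need not separate. Those that fell were H2ac18, H2ac19 and H2bc21; the 2 detected probes of H2bc21 were called in opposite directions (log2 fold changes -0.43 and 2.03), and its call was lost without precursor replicate 2 (limma adjusted p = 0.0736) or CCR9+ pDC replicate 1 (0.0526) and under median scaling (0.448). The BCL2 and caspase list moved both ways, 6 higher and 8 lower of 21 (camera adjusted p = 0.765, direction down; median 0.22, mean -0.12, fry's direction up), and its median ranged from -0.24 to 0.44 over the alternatives. Bcl2, already seen, was 12.2-fold higher. Its relatives Bcl2a1d and Bcl2a1b, close paralogs of each other, differed by -3.00 and -2.81 on the log2 scale. With probe means Bcl2a1d differed by -2.31, and Bcl2a1b was above background on 2 precursor arrays. Cell cycle genes moved with the DNA repair and histone lists (median 2.26). The histone genes H2ac12, H2ac11, H2ac15 and H2ac21 had been seen among the highest changes before the histone list was made.

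Immediate early and stress genes varied between the arrays of each group (SD of the list mean 0.70 in CCR9+ pDCs and 0.82 in precursors, n = 3). The mean signal of the 19 genes was 9.74, 10.49 and 11.15 on CCR9+ pDC replicates 1, 2 and 3 and 8.94, 9.65 and 10.57 on precursor replicates 1, 2 and 3 (log2). In both groups the lowest mean belonged to replicate 1 and the highest to replicate 3, and same-numbered arrays differed by -0.80, -0.84 and -0.58 (precursor minus CCR9+ pDC), a hint from the data and not from the design.

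A core macrophage list outside the fixed lists, whose values had not been seen, had a median log2 fold change of -0.83 (-0.76 at the bounds), and 21 of 24 genes were lower in precursors (17 called lower; Tspan14 and Mr1 called higher, Mr1 at least 1.11-fold). The median was -0.39 without background correction and -0.42 with the authors' processed values. Its most abundant genes in CCR9+ pDC arrays changed unequally: Cd164 stood at 13.98 in CCR9+ pDCs and 13.72 in precursors (limma adjusted p = 0.0797), Pla2g15 at 11.98 and 11.10, and Trf at 11.96 and 9.08 (log2). The largest falls in the list were those of Siglec1, at least 10.6-fold lower and not above background in precursors, Trf (7.38-fold) and Pld3 (5.35-fold), while 5 genes were not called. In all, 15 of the 24 were above background on all precursor arrays. Mr1 was not called without precursor replicate 1 (limma adjusted p = 0.0914) or 3 (0.0695) or CCR9+ pDC replicate 2 (0.0786), nor with the authors' processed values (0.0765), an intensity trend and robust prior (0.0663) or no background correction (0.0718).

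Macrophage genes were higher in CCR9+ pDC arrays, and normalization and background correction do not account for it: over 5 other settings the highest median of the macrophage markers was -1.78. A lower share of pDCs with every other marrow cell type in their place stays open: the macrophage median lay below that of every other marker list, by more than the SD of 2.13 of the macrophage markers for erythroid (-2.24, one-sided permutation p = 0.00397), T and NK (-2.47, p = 0.00078) and plasma cell markers (-2.53, p = 0.0128), but within it for granulocyte (-1.93, p = 9e-05) and basophil, mast cell and eosinophil markers (-1.33, p = 0.0308). This test first pooled granulocyte, erythroid, T and NK markers, and the difference of -2.21 (one-sided permutation p = 1e-05, the smallest that 1e+05 draws over genes can give) was then read as excluding the explanation; asking for a gap beyond the SD from each list, a rule set after these values were seen, reversed that reading. The pDC surface genes, which a lower share alone would lower in CCR9+ arrays, were higher there (median -1.08). This does not decide the question. Their level per cell may differ between the groups, and other cells in the sort may express some of them. Macrophage RNA in the CCR9+ sort may account for the pattern, as a hypothesis. The core list met it at -0.83 but would not have met it, at the -0.5 asked for, without background correction (-0.39). Expression of these genes by CCR9+ pDCs was not tested and stays open. The sort on CCR9 named in the labels should exclude macrophages that lack it, but its purity was not measured here. Granulocyte markers had a median log2 signal of 10.83 in the CCR9+ arrays.

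Cell cycle genes were higher in precursor arrays. Over 5 other settings the lowest list median was 1.75, so normalization and background correction do not account for it. Dilution of pDC RNA by other RNA in the CCR9+ arrays would lower pDC transcription factors alike, but their median lay below that of the cell cycle genes (difference -2.25; one-sided permutation p = 1e-05, the smallest these draws can give). More erythroid or granulocyte RNA in the CCR9- sort is argued against, since 1 of 28 of these markers had a higher mean in precursor arrays. The lists do not separate dividing precursors from mature cells. More RNA of mature cells in the CCR9+ arrays could hide some dividing precursors in the CCR9- sort, so these are not excluded. More cycling cells in the CCR9- population may explain the pattern, as a hypothesis; dividing cells of other types were not tested.

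Surface and function genes of pDCs were lower in precursor arrays. Dilution of pDC RNA in the CCR9- arrays would lower transcription factors as well. Their median lay 1.09 above that of the surface genes (one-sided permutation p = 0.0115). That gap exceeds the SD of 0.874 of the transcription factors but lies within the SD of 1.24 of the surface genes. The SD condition was added after the values were seen, and dilution stays open. Macrophage RNA in the CCR9+ sort stays open: 10 list members taken not to be macrophage genes had a median of -0.83, and 8 of them were lower, but no macrophage profile measured here shows which of them macrophages lack. A difference in pDC maturation between the groups is among the open explanations and was not tested.

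With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one mixes arrays of both groups, which puts the group difference into the residual spread. Low gene counts in those splits follow from this and decide nothing about chance. The real split gave 3420 genes and the highest other 0, and 1221 genes at least 2-fold against 0; in both cases 1 of the 10 splits, the real one, gave as many. For the fixed lists the real split gave 16 and the highest other 18, and 4 of the 10 splits gave at least as many. The other splits mix the groups unevenly, so part of the group difference remains between their sides. Camera compares genes with each other and can still call lists there. The list counts of these splits therefore decide nothing about chance either.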
